A study of Drosophila melanogaster with 6 samples.

How the data were processed

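The samples were circulating hemocytes of wandering larvae of Drosophila melanogaster, 3 control and 3 Idh-R195H samples, grouped by the genotype in the labels and named by the replicate number there. Per the labels' protocols, egg lays of 24 hours at 29 °C gave larvae that were harvested on day 7, the hemocytes of 400 larvae were pooled per sample by opening the rear of each larva while sparing the lymph gland, and 6 ug of total RNA was labelled with biotin for a 1-colour array. The labels call the samples biological replicates. Per the submitters' processing notes the tool Partek 6.0 was used, with no role given; the method that made the summarised values, and the array's genome build, are not given in the sources used here, so no coordinates are reported.

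The deposited values are linear probe set intensities, 1 per probe set and array. From the values, every array has the same trimmed mean (500.0, leaving out 2% at each end), so the authors or their software scaled each array to a common mean; distributions were not made equal, and the largest intensity differed between 37577.7 and 56234.5. Because that mean leaves out the brightest 2% of probe sets, a change in those alone hardly moves the scaling. A change in many of the bright probe sets below them moves all other genes on an array. No count or detection call was used here, and signal over background could not be stated per probe set; the share of probe sets below an intensity of 100 describes the dim part. All columns of per-sample values were used.

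Of 18952 probe sets, 183 were array controls and were left out, leaving 18769 tested. Gene names came from the array's platform annotation, which can be old: 13646 tested probe sets had 1 gene symbol, 402 had several and 4721 had none in the table used here. Of the first, 13543 matched a RefSeq gene table (Release 6 assembly, used only for names, list membership and the chromosome of a gene) by gene identifier, and 0 symbols changed. Probe sets with several symbols or none stayed in the tests and are not named; they made up 102 of the changed probe sets. Of the single-gene probe sets, 1351 have a name that marks probes shared between transcripts or similar sequences. Where a gene had several probe sets, the one with the highest mean over the 6 arrays stands for it, which gave 11982 genes. Other, dimmer probe sets of 5 passing named genes had the same sign without passing: egr (log2 fold change 4.04, adjusted p = 0.0577), TpnC73F (0.53, adjusted p = 0.268), Ptp61F (0.59, adjusted p = 0.295), fok (-0.91, adjusted p = 0.266) and kn (0.80, adjusted p = 0.137). Of those not passing, Mmp2 had one of opposite sign, and the 7 others for trol went both ways.

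Intensities were transformed as log2(value + 1), so fold changes understate the change of dim genes. Idh-R195H was compared with control by limma 3.58.1 (R 4.3.3), with a linear model on group, empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over all tested probe sets; a probe set was called changed at an adjusted p below 0.05. Log2 fold changes are Idh-R195H minus control, and errors marked SE are limma's moderated standard errors. Before the data were examined, 42 gene lists were fixed, of which 40 had at least 3 measured genes and were tested; 1 held Idh alone, and the list of replication-dependent histones had no single-gene probe set used here. Lists were tested with camera at a preset inter-gene correlation of 0.01 on 1 probe set per gene, adjusted over the 40 lists, and again with an estimated correlation, with which no list passed. The rule for named genes, fixed at the same time, took the 12 largest increases and the 12 largest decreases among single-gene probe sets with an adjusted p below 0.05 and non-overlapping arrays, Idh, and up to 4 members of each list described, those with the largest absolute log2 fold change, whether or not they passed. Members of other lists are named only where they were among those 4 and passed.

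The steps were tested on simulated arrays with the real means and spread, and with noise drawn independently for each probe set. With 200 of 18769 probe sets changed, the test recovered 0% of those with a log2 change of 1, 31.3% at 2 and 57.6% at 3, and called 5 unchanged probe sets; with no change it called 0. Small changes of single probe sets were therefore mostly out of reach with 3 arrays per group. The list test called 0 lists with no change simulated and gave an adjusted p of 2.74e-18 for a 14-gene list shifted by 1. Simulated genes were not correlated, whereas the estimated correlation of the real lists reached 0.73 for salivary gland markers. The simulation therefore does not show how often the list test calls correlated lists by error.

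Alternatives fixed beforehand were quantile normalization, centring on array medians, leaving out dim probe sets, an intensity trend with a robust prior, array weights, the replicate number as a block, a constant of 16, leaving out each array, other thresholds and 1 probe set per gene, and for lists an estimated correlation, the directional test fry and the mean of all probe sets of a gene. Scaling on hybridisation controls, and the use of control replicate 1 as the only control array, were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. One gene family that passed a later test is not reported here.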

Results

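Gene expression was measured in circulating hemocytes, the blood cells of the fruit fly Drosophila melanogaster, collected from wandering larvae of the third instar. Both genotypes carried the hml-Gal4 driver, which switches on transgenes in hemocytes, together with a green fluorescent reporter. The 3 Idh-R195H samples also carried a transgene for Idh-R195H, the fly counterpart of a cancer-associated mutant of human IDH1, and the 3 control samples carried the driver and reporter alone. Each sample was a pool of hemocytes from 400 larvae raised at 29 °C and harvested on day 7, and each was hybridised to 1 array. The deposited values were probe set intensities, with an array median between 76.0 and 107 and between 49.0% and 54.1% of probe sets below an intensity of 100. The number of arrays limited the precision. The comparison of the 2 genotypes asked which genes and pathways were higher or lower in hemocytes that expressed Idh-R195H.

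The single probe set for Idh (CG7176), which encodes isocitrate dehydrogenase, rose from an intensity of 4034.5 ± 245 (SD, n = 3) in control to 9967.2 ± 941 (SD, n = 3) in Idh-R195H hemocytes. This was a 2.47-fold increase, with a log2 fold change of 1.30 ± 0.19 (SE) and an adjusted p of 0.0319 in limma. All 3 Idh-R195H arrays lay above all 3 control arrays, which is the direction the genotype labels imply. The array annotation used here does not say whether the probe set matches the transgene transcript, so the value may combine transgene and endogenous RNA. The adjusted p in limma ranged over the alternative settings from 0.00112, with array weights, to 0.173, with the replicate number as a block. The estimate of the array weights did not converge. The call was lost without any 1 array other than control replicate 1, where the log2 fold change ran from 1.23 to 1.35. Scaling on the hybridisation controls gave a log2 fold change of 2.25.

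Idh-R195H hemocytes differed broadly from control hemocytes. Of 18769 probe sets tested, 356 were higher and 228 were lower in Idh-R195H hemocytes at an adjusted p below 0.05. In total 584 probe sets changed, all of them by at least 2-fold, and 108 rose and 38 fell by at least 8-fold. With 1 probe set per gene, these calls covered 275 genes that rose and 177 that fell. The genes that rose most included ItgaPS4 (CG16827) and ItgaPS5 (CG5372), 2 integrin alpha subunits, at 35.2-fold and 31.6-fold. They also included wun2 (CG8805), a lipid phosphate phosphatase, at 46.4-fold, and BomS2 (CG18106), a secreted peptide of the Toll immune response, which went from 22.2 ± 19.4 to 2237.2 ± 1543.9 (SD, n = 3 each). The transcript of trio (CG18214) went from 5.02 ± 5.72 to 391.9 ± 14.7, and that of Ocho (CG3396), a gene of the Bearded family, from 17.7 ± 19.1 to 1062.9 ± 107 (SD, n = 3 each). CG31219 went from 50.6 ± 33.6 to 9555.2 ± 917 and CG14610 from 748.7 ± 380 to 22998.6 ± 1213.5 (SD, n = 3 each). Mean intensities went from 46.1 to 5967.2 for CG9733, from 18.6 to 1535.7 for CG4757, from 16.2 to 791.9 for CG15740 and from 15.1 to 528.6 for CG3397. The control means of 8 of the 12 genes lay below 80.2, the lowest median of a control array, so their folds depend on the added constant and their order is not known.

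Among the 12 genes past the threshold with the largest decreases, Sgs7 (CG18087), which encodes a salivary gland glue protein, had a log2 fold change of -5.32 ± 0.86 (SE). Its intensity was 8301.7 in control replicate 1, 47024.8 and 54781.2 in the other control arrays, and 792.9 ± 531 (SD, n = 3) in Idh-R195H hemocytes. NT5E-2 (CG30104), a nucleotidase gene, had a log2 fold change of -4.55 ± 0.52 (SE), and yellow-h (CG1629), a member of the yellow gene family, went from 888.1 ± 619 to 21.4 ± 3.14 (SD, n = 3 each). Cpr66Cb (CG7076), a cuticle protein gene, had a log2 fold change of -4.13, Alp7 (CG3292), an alkaline phosphatase gene, of -3.71, and sro (CG12068), which acts in ecdysone synthesis, of -3.60. The log2 fold changes of CG33458 and CG31999 were -4.22 and -3.97. Mean intensities went from 506.5 to 36.6 for Ttc26 (CG4525), a gene of intraflagellar transport, from 1126.2 to 64.2 for mat (CG13905), from 102.9 to 4.80 for CG13312 and from 186.9 to 14.6 for hoe2 (CG15624), where the dim Idh-R195H values leave the fold uncertain. All 24 of these genes had non-overlapping arrays between the genotypes, which the naming rule required; over all probe sets 28.8% did not overlap, against 10% by chance.

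**Figure D1:**
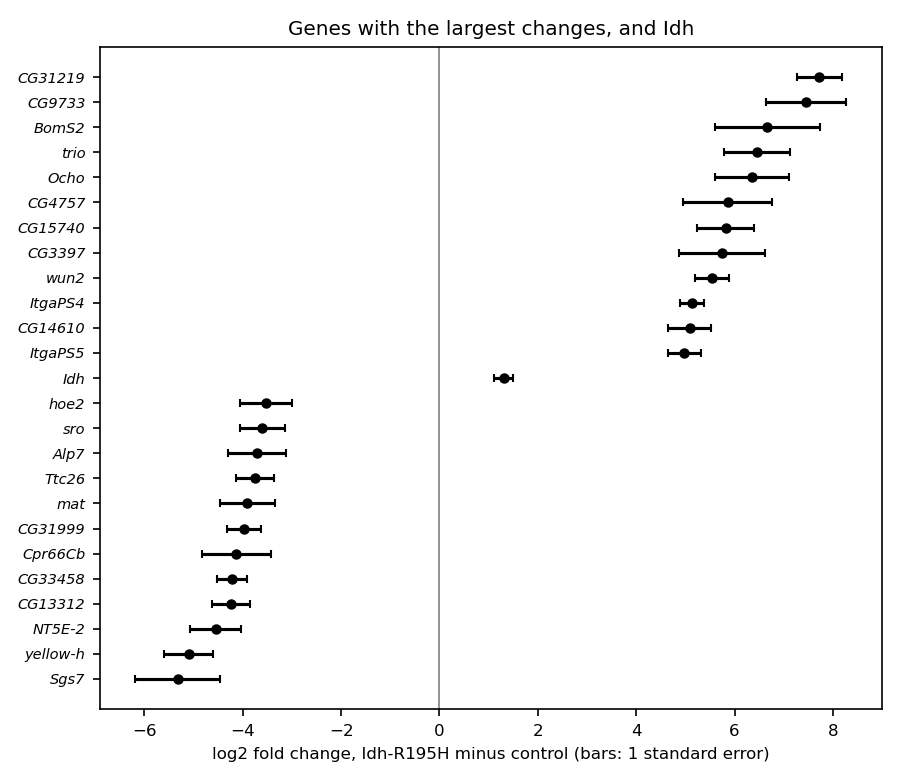
Log2 fold change (horizontal axis, Idh-R195H minus control, 3 arrays each) of the 12 genes with the largest increase, the 12 with the largest decrease and Idh; points are limma estimates and bars are 1 standard error. ItgaPS4 stands at 5.14 and Sgs7 at -5.32, and Idh lies between the groups at 1.30; estimates of genes with dim arrays depend on the added constant.

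The number of called probe sets depended strongly on single arrays, on the scaling and on the test. Of the 56 named genes that passed the threshold besides Idh, 0 passed in every alternative. With the replicate number as a block 0 probe sets were called, so no gene could pass in all. ItgaPS4 passed in 14 of 15 alternatives. The number of called probe sets ran from 11 without Idh-R195H replicate 2 to 870 without control replicate 1, and was 155 and 300 without control replicates 2 and 3, and 86 and 68 without Idh-R195H replicates 1 and 3. It was 6252, with 6081 higher and 171 lower, after scaling on the hybridisation controls, and 7489 with array weights, whose estimate did not converge. Over all probe sets the median log2 fold change was -0.11 with the deposited scaling, 0.02 after quantile normalization and 0.15 after centring each array on its median. The last of these gave 318 higher and 111 lower. Scaling on the hybridisation controls moved this median to 0.84 and list medians with it, to 3.74 for lamellocyte markers, 1.75 for the cell cycle, 1.76 for JAK/STAT, 1.39 for ribosome biogenesis and 1.03 for mitochondrial ribosomal proteins. The calls of GstE5, fok, Tpi, wgn, SPARC, Lpin and Tm2 were lost under this scaling. The camera tests of gene lists below compare each list with the other genes and so are relative to that shift. The test fry, given for some lists, compares a list with no change and so depends on the scaling. Added hybridisation controls, bacterial transcripts put on every array, were 1.93-fold brighter on the control arrays in the median of 14 probe sets. The polyA controls added to the RNA were 2.62-fold brighter in the median of 24. The ratio of 3' to 5' probe set intensity, which rises as RNA is degraded or incompletely copied, was 4.78 ± 1.26 for Act5C on control arrays and 2.28 ± 0.13 on Idh-R195H arrays (SD, n = 3 each). Control arrays correlated with each other at 0.876 to 0.928 (Pearson, across probe sets on the log2 scale, which are not independent replicates), Idh-R195H arrays at 0.952 to 0.957, and arrays of different genotype at 0.889 to 0.913. Control replicate 1 correlated better with each Idh-R195H array (0.900 to 0.913) than with control replicate 3 (0.876), and at 0.908 with control replicate 2.

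Markers of lamellocytes, the large flat hemocytes that encapsulate parasites and are rare in unchallenged larvae, rose together in Idh-R195H hemocytes. All 14 measured members had a positive log2 fold change, with a median of 2.79, and 8 passed over all probe sets; adjusted over the list alone, 14 passed. Besides ItgaPS4 and ItgaPS5, PPO3, a lamellocyte prophenoloxidase, went from an intensity of 570.3 ± 110 to 16363.2 ± 2167.6, and mdu from 424.5 ± 136 to 6485.7 ± 1041.9 (SD, n = 3 each), which were 28.9-fold and 15.7-fold increases. The list stood above the other genes with a camera adjusted p of 3.52e-16 and a preset correlation; the adjusted p was 0.0592 with an estimated correlation. The call held in the other 16 alternatives for this list, with a lowest adjusted p of 8.23e-18. Other differences of the control arrays moved with this group. Their 3' to 5' ratios were higher, as was their salivary gland, fat body and midgut signal (median log2 fold changes of -5.59, -1.91 and -1.49). The mean log2 value of the list relative to the array median was 3.72, 3.30 and 3.02 on control replicates 1, 2 and 3. The array medians themselves were at intensities of 80.2, 107 and 104, so part of this fall lies in the reference.

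Markers of plasmatocytes, the phagocytes that make up most larval hemocytes, showed no common shift. None of 16 measured members passed over all probe sets, while 1 was higher and 4 were lower when adjusted over the list alone, and the list's median log2 fold change was -0.10 (camera adjusted p = 0.506). NimC2, a phagocytosis receptor, was at 1871.1 ± 870 in control and 262.9 ± 217 in Idh-R195H hemocytes (adjusted p = 0.0761), and Sr-CI, a scavenger receptor, at 7447.5 ± 2220.1 and 16967.8 ± 1717.2 (SD, n = 3 each; adjusted p = 0.0844). The log2 fold change was -1.62 ± 0.46 for crq and 1.81 ± 0.94 for NimC4 (SE), neither past the threshold. Among 8 markers of crystal cells, which carry out melanization, CG17109 rose by 2.70 ± 0.45 and fok had a log2 fold change of -2.04 ± 0.30 (SE), and the list did not pass (adjusted p = 0.131; 1 higher and 4 lower when adjusted over the list alone). PPO2, the main crystal cell prophenoloxidase, was at 34029.7 ± 1032.9 in control and 19164 ± 4673.2 in Idh-R195H hemocytes (SD, n = 3 each; adjusted p = 0.145), and CG7860 had a log2 fold change of -1.48 ± 0.36 (SE, adjusted p = 0.0975). Of 10 markers of blood progenitors and their niche, Pvf2, a PDGF/VEGF-like growth factor, rose 12.6-fold, and kn, a transcription factor of the niche, rose from a dim 40.6 ± 1.38 to 89.2 ± 2.65 (SD, n = 3 each). Tep4 and Ance were at log2 fold changes of 1.12 ± 0.34 and -1.02 ± 0.27 (SE) without passing, and the list did not pass (adjusted p = 0.247; 3 higher and 1 lower when adjusted over the list alone), although it passed upward with the test fry (adjusted p = 0.0395).

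**Figure D2:**
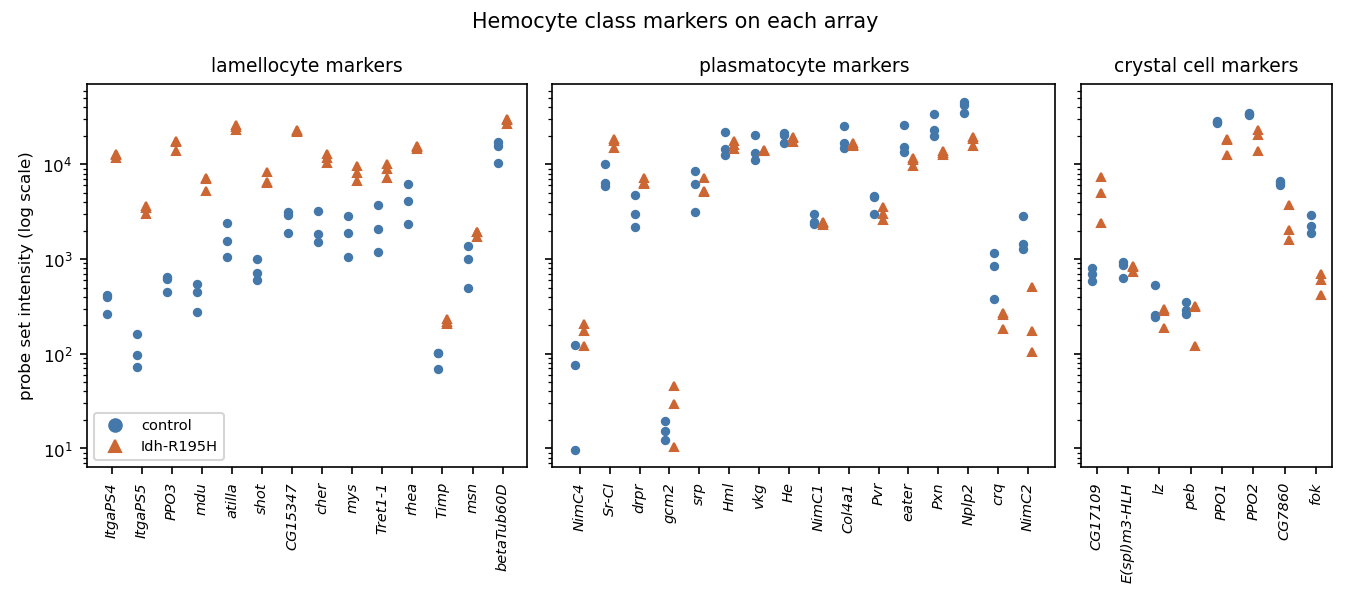
Probe set intensity (vertical axis, logarithmic) of each measured marker of 3 hemocyte classes on the 3 control arrays (circles) and 3 Idh-R195H arrays (triangles), with genes along the horizontal axis ordered by log2 fold change. The Idh-R195H arrays lie above the control arrays for the 14 lamellocyte markers, whereas plasmatocyte markers go both ways.

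Genes of the cell cycle and DNA replication were higher as a group. Of 24 measured members, 23 had a positive log2 fold change, with a median of 0.80; none passed over all probe sets and 13 passed when adjusted over the list alone. The mitotic regulators tum and CycB had log2 fold changes of 1.66 ± 0.33 and 1.55 ± 0.31 (SE, adjusted p = 0.0613 for both), Incenp of 1.06 ± 0.25 and CycE of 1.08 ± 0.48. The list's camera adjusted p was 6.96e-09, and the adjusted p was 0.637 with an estimated correlation, the highest of the alternatives, the lowest being 3.11e-09. The higher Act5C ratios of the control arrays (4.78 against 2.28) and their higher salivary gland, fat body and midgut signal (median log2 fold changes of -5.59, -1.91 and -1.49) moved with this group and with the next. Genes of ribosome biogenesis were also higher as a group (27 measured, 22 positive, median 0.44, none passing singly with either adjustment; camera adjusted p = 0.00601). This call was lost without control replicate 3 (adjusted p = 0.0778), with an estimated correlation (adjusted p = 0.751), with the test fry (adjusted p = 0.25) and with control replicate 1 as the only control, which had the lowest Act5C ratio of the controls (3.72) and where the direction turned (median 0.03, adjusted p = 0.92), and over all alternatives the adjusted p ran from 4.35e-05 to 0.92. Its members with the largest log2 fold changes were l(2)k09022 at 1.00 ± 0.27, Nopp140 at 0.99 ± 0.36, mod at 0.87 ± 0.28 and Polr1A at 0.77 ± 0.34 (SE).

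Cytosolic ribosomal protein genes were lower relative to other genes with the deposited scaling (median log2 fold change -0.64, 38 of 41 negative, camera adjusted p = 1.67e-10). Their median was -0.04 after quantile normalization, against 0.02 for all probe sets. After scaling on the hybridisation controls it was 0.30, against 0.84 for all probe sets. These genes were very bright, with median intensities of 35967.6 in control and 22772.4 in Idh-R195H hemocytes. The largest intensity of an array was 52842.5 to 56234.5 in control and 37577.7 to 40283 in Idh-R195H. The fall therefore cannot be told apart from the lower top of the Idh-R195H intensity range. The call was lost with quantile normalization (adjusted p = 0.23) and with an estimated correlation (adjusted p = 0.637), and the lowest adjusted p of the alternatives was 7.65e-21. None passed over all probe sets, and 30 were lower when adjusted over the list alone. The log2 fold changes of RpL37-2, RpL22-like, RpS5b and RpL24-like were -1.18 ± 0.72, -1.17 ± 0.75, -1.06 ± 0.64 and -0.79 ± 0.26 (SE). Mitochondrial ribosomal protein genes had a median of 0.08, 50 of 69 positive, none passing singly with either adjustment, and a camera adjusted p of 0.0162 upward. That call was lost without control replicate 2 (adjusted p = 0.208), without Idh-R195H replicate 1 (adjusted p = 0.0967), with quantile normalization (adjusted p = 0.186), without dim probe sets (adjusted p = 0.0961), with fry (adjusted p = 0.283), with 1 control array and with an estimated correlation (adjusted p = 0.815). The lowest camera adjusted p of the alternatives was 4.04e-06, with array weights. The members mRpS18C and mRpS30 were at 0.98 ± 0.21 and 0.87 ± 0.20, mRpS9 at 0.63 ± 0.19 and mRpS6 at -0.76 ± 0.21 (log2 fold change with SE). Both ribosomal protein groups moved with the higher Act5C ratios of the control arrays (4.78 against 2.28). They also moved with the higher salivary gland, fat body and midgut signal of those arrays (median log2 fold changes of -5.59, -1.91 and -1.49).

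Signalling genes changed in a few members. In the list of the JAK/STAT pathway and its targets, upd1, a ligand of the pathway, rose from an intensity of 10.5 to 57.9 (both means), and Ptp61F, a phosphatase that acts on it, from 448.5 ± 105 to 1308.0 ± 141 (SD, n = 3 each). Of 9 measured members 7 were positive, 3 passed when adjusted over the list alone, and the median was 0.81 (camera adjusted p = 0.0208). The call was lost with an estimated correlation (adjusted p = 0.637), without control replicate 3 (0.0802), without dim probe sets (0.151), with array weights (0.057) and with 1 control array (0.479), and 0.00131 was the lowest adjusted p of the alternatives. The higher Act5C ratios of the control arrays (4.78 against 2.28) and their higher salivary gland, fat body and midgut signal (-5.59, -1.91 and -1.49) moved with this group too. The stress peptide genes TotB and TotC had log2 fold changes of 3.26 ± 1.51 and 2.88 ± 1.26 (SE) and did not pass. In the list of the JNK pathway and its targets, egr, a TNF ligand, rose 5.84-fold and cher, a filamin gene, rose 5.54-fold, while wgn, a TNF receptor gene, went from 160.0 ± 49.2 to 37.8 ± 11.1 (SD, n = 3 each). Another TNF receptor gene, grnd, was at -1.76 ± 0.43 (SE, adjusted p = 0.0992), and the list did not pass (14 measured, 11 positive, 2 higher and 2 lower when adjusted over the list alone, median 0.48, adjusted p = 0.0871). It shared cher and msn with the lamellocyte list.

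Immune peptide genes went in both directions. Among 20 measured genes of humoral immunity, BomS2 rose, and Mtk, which encodes metchnikowin, went from 16582.0 ± 2815.7 to 2261.1 ± 992 (SD, n = 3 each), a log2 fold change of -2.95 ± 0.37 (SE). DptB and AttD, with log2 fold changes of -2.79 (adjusted p = 0.376) and -2.57 (adjusted p = 0.49), did not pass. The list's median and mean were -0.21 and -0.09, its test pointed upward, and it did not pass (adjusted p = 0.619); 1 member was higher and 1 lower when adjusted over the list alone. Among 17 genes of the basement membrane and collagen processing, SPARC, a collagen-binding protein gene, was 2.73-fold lower (log2 fold change -1.45 ± 0.20, SE), but at -0.50 after scaling on the hybridisation controls (adjusted p = 0.109, the range over the alternatives being 0.00106 to 0.157). Mmp2 was at 3.34 ± 0.84, trol at -2.05 ± 0.65 and Ppn at 1.00 ± 0.29 without passing, although a dimmer probe set for Mmp2 was at -1.83. The list did not pass (adjusted p = 0.738; 1 lower when adjusted over the list alone).

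Metabolic genes close to the Idh reaction were not shifted as groups in the camera test. None of 16 other genes of the tricarboxylic acid cycle passed over all probe sets, 2 were higher when adjusted over the list alone, and the list's median was 0.26 (adjusted p = 0.0908). In the list for 2-hydroxyglutarate, glutamate and glutamine metabolism, Gs1, a glutamine synthetase gene, went from 16797.0 ± 2774.5 to 2533.4 ± 1194.3 (SD, n = 3 each), a log2 fold change of -2.81 ± 0.37 (SE). The paralogue Gs2 was at -2.67 ± 0.49, Gabat at -1.69 ± 0.42 and P5CDh1 at 1.35 ± 0.27 (SE), none of which passed. The list's adjusted p was 0.725, with 3 of 11 higher and 3 lower when adjusted over the list alone. In the redox defence list, Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, rose 2.54-fold, while the metallothionein gene MtnB had a log2 fold change of -3.14 ± 0.27 (SE) and the sulfiredoxin gene Srx went from 2702.4 ± 645 to 674.6 ± 163 (SD, n = 3 each). Sod3 was at -1.55 ± 0.42 without passing. Adjusted over the list alone 3 of its 15 members were higher and 6 lower. The list did not pass with camera (adjusted p = 0.325, or 0.735 with an estimated correlation), although it passed downward with fry (adjusted p = 0.0131). Its median was -0.37 with the deposited scaling, which fry used, but 0.58 after scaling on the hybridisation controls.

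Glutathione S-transferase genes were lower as a group relative to other genes (34 measured, 26 negative, median log2 fold change -0.58, camera adjusted p = 0.0162). After scaling on the hybridisation controls their median was 0.37, against 0.84 for all probe sets. The call was lost without control replicate 1 (adjusted p = 0.0506), with 1 control array (adjusted p = 0.106) and with an estimated correlation (adjusted p = 0.537), and 0.00243 was the lowest adjusted p of the alternatives. GstT4 and GstE5 had log2 fold changes of -2.93 ± 0.53 and -1.75 ± 0.26 (SE), while GstE6 rose by 2.25 ± 0.31 (SE), and GstE7 was at -1.74 ± 0.39 without passing. Adjusted over the list alone, 3 were higher and 12 lower. The higher fat body and midgut signal of the control arrays (median log2 fold changes of -1.91 and -1.49) moved with this group.

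Markers of 4 other larval tissues were higher on control arrays as lists, while the muscle, neural and imaginal disc lists did not pass. All 9 measured salivary gland markers were negative (median log2 fold change -5.59, from -6.90 to -2.99 over the alternatives with a list test; camera adjusted p = 4.69e-05; adjusted p = 0.686 with an estimated correlation). Sgs7 passed over all probe sets and 8 passed when adjusted over the list alone. The glue protein genes Sgs4, Sgs8, Sgs5 and Sgs3 had log2 fold changes of -6.32 ± 1.47, -6.19 ± 1.16, -5.93 ± 1.16 and -5.72 ± 1.22 (SE), without passing singly over all probe sets. All 11 fat body markers were negative (median -1.91, from -2.48 to -1.16; camera adjusted p = 0.000945; adjusted p = 0.686 with an estimated correlation), and 1 passed when adjusted over the list alone. Fbp1 was at 24101.3 ± 12209.4 in control and 6442.2 ± 7129.8 in Idh-R195H hemocytes (SD, n = 3 each). Fbp2, sug and AkhR were at log2 fold changes of -2.36, -2.29 and -2.19, none of the 4 passing. Of 14 midgut markers 11 were negative (median -1.49, from -2.81 to -0.89; camera adjusted p = 0.0208; adjusted p = 0.686 with an estimated correlation), and none passed singly with either adjustment. The digestive protease genes Jon25Bi, Jon65Aiv, thetaTry and Jon65Aiii were at -5.13 ± 1.91, -3.99 ± 1.43, -3.85 ± 0.82 and -3.75 ± 1.46 (log2 fold change with SE). Of 16 cuticle and epidermis markers 14 were negative (median -1.07, from -1.15 to -0.63; camera adjusted p = 0.0162; adjusted p = 0.537 with an estimated correlation), and 3 passed when adjusted over the list alone. Cpr49Ac was at -1.69 ± 0.33, obst-E at -1.54 ± 0.38, Cpr97Eb at -1.52 ± 0.76 and serp at -1.34 ± 0.29. For these 4 lists the values with an estimated correlation were the highest adjusted p of the alternatives, and the lowest were 1.51e-09, 3.46e-06, 0.000653 and 0.00478 in the same order. The midgut call was lost without control replicate 3 (adjusted p = 0.0781) or Idh-R195H replicate 1 (adjusted p = 0.0531), and the cuticle call without control replicate 2 (adjusted p = 0.0557). With fry the salivary gland, fat body and midgut calls were lost (adjusted p = 0.0539, 0.078 and 0.0996), and with 1 control array the fat body, midgut and cuticle calls (0.106, 0.107 and 0.148). The midgut and cuticle calls were lost without dim probe sets (0.054 and 0.273), and the midgut call with array weights (0.111). After scaling on the hybridisation controls the medians were -4.64 for salivary gland, -0.96 for fat body, -0.54 for midgut and -0.12 for cuticle markers.

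**Figure D3:**
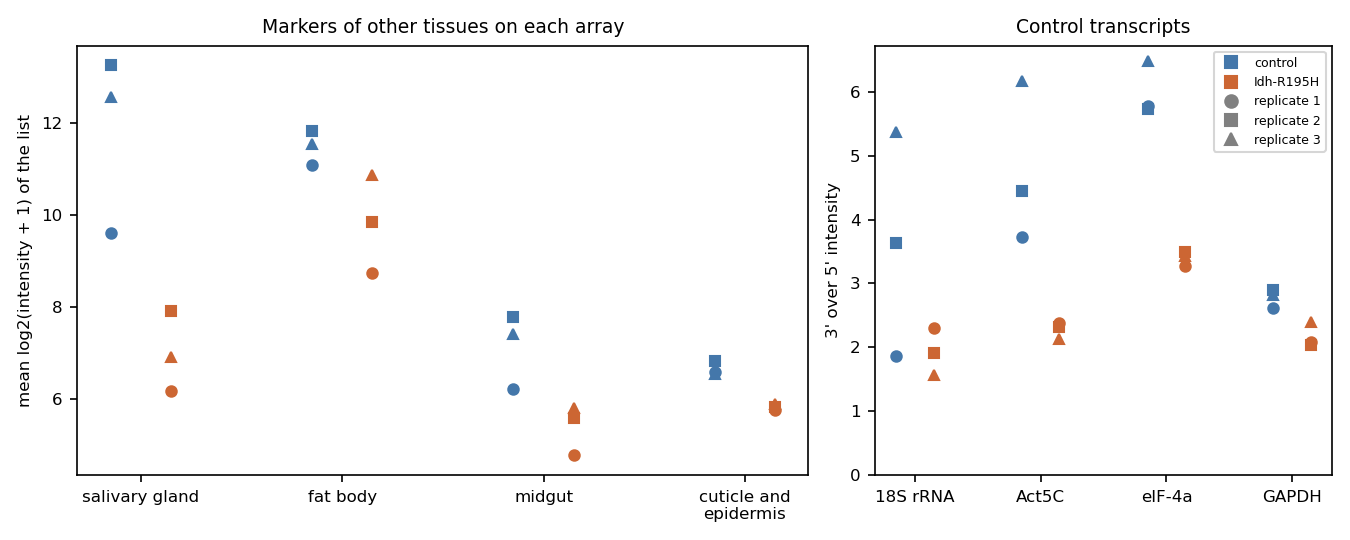
Left, mean log2(intensity + 1) of the measured markers of 4 other tissues on each array; right, ratio of 3' to 5' probe set intensity of 4 control transcripts, with colour for genotype and symbol shape for replicate number. Salivary gland markers averaged 9.62, 13.3 and 12.6 on control replicates 1, 2 and 3 and at most 7.91 on an Idh-R195H array, and the Act5C ratio was at least 3.72 on control arrays and at most 2.38 on Idh-R195H arrays.

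Among 14 muscle markers, TpnC73F, a troponin C gene, rose 12.5-fold and Tm2, a tropomyosin gene, went from a dim 59.55 ± 10.95 to 13.98 ± 6.92 (SD, n = 3 each). Mlc1 and Mf were at -1.92 ± 0.43 and -1.88 ± 0.41 (SE) without passing, and the list did not pass (median -0.72, or 0.23 after scaling on the hybridisation controls; adjusted p = 0.0895), with 1 member higher and 4 lower when adjusted over the list alone. Genes of the ecdysone response, which times larval stages and induces glue genes, were lower as a group relative to other genes (16 measured, 11 negative, median -0.58, camera adjusted p = 0.0208). After scaling on the hybridisation controls their median was 0.37, against 0.84 for all probe sets. The call was lost without control replicate 1 (adjusted p = 0.255), without control replicate 2 (adjusted p = 0.0557) and with an estimated correlation (adjusted p = 0.686), and 0.00171 was the lowest of the alternatives. ImpE3, MsrA and Eip78C passed, from 408.6 ± 48.2 to 45.6 ± 4.51, from 2607.1 ± 725 to 428.0 ± 30.4 and from 373.9 ± 188 to 66.8 ± 15.3 (SD, n = 3 each), as did 3 genes adjusted over the list alone, and Hr3 was at -1.97 ± 0.90 without passing. The higher salivary gland signal of the control arrays moved with this group.

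The remaining lists did not pass the camera test. Single members passed in several of them. The small heat shock genes Hsp26 and Hsp27 were 4.87-fold and 4.31-fold lower (list adjusted p = 0.0888). CG11899 and CG6287, genes of serine synthesis in the list of ATF4 and amino acid stress, were 5.86-fold and 4.83-fold lower (list adjusted p = 0.217). Tpi, a glycolytic enzyme gene, was 2.09-fold lower (glycolysis list adjusted p = 0.506), and Lpin, a lipin gene, was 2.25-fold lower (lipid metabolism list adjusted p = 0.725). After scaling on the hybridisation controls these genes were at log2 fold changes of -0.12 (adjusted p = 0.682) and -0.22 (adjusted p = 0.416), the highest of their alternatives. The lowest adjusted p values in limma were 0.00125 and 0.00137, each with array weights. Snap25, a gene of synaptic vesicle fusion, rose from a dim 47.2 ± 11.8 to 187.2 ± 21.7 (SD, n = 3 each; neural marker list adjusted p = 0.903). In turn egr was the passing member of the list of apoptosis and p53 targets (adjusted p = 0.75). Of the other lists, with no passing member, the adjusted p was 0.0635 for oxidative phosphorylation, 0.17 for 2-oxoglutarate-dependent dioxygenases, 0.217 for the proteasome, 0.251 for the unfolded protein response and 0.269 for insulin, TOR and energy stress. It was 0.494 for sex-linked dosage markers, 0.725 for DNA repair, 0.756 for NADPH supply and for the lysosome and phagosome, 0.769 for the hypoxia response and for imaginal disc and tracheal markers, and 0.903 for the vacuolar ATPase. Adjusted over the list alone, 1 to 3 members were lower for heat shock, ATF4, lipid metabolism, glycolysis and insulin, and 1 or 2 were higher for neural, apoptosis, lipid metabolism, insulin, lysosome and imaginal disc markers, with 0 in the others. In the neural, NADPH supply, DNA repair and imaginal disc lists the median and the test had opposite signs.

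**Figure D4:**
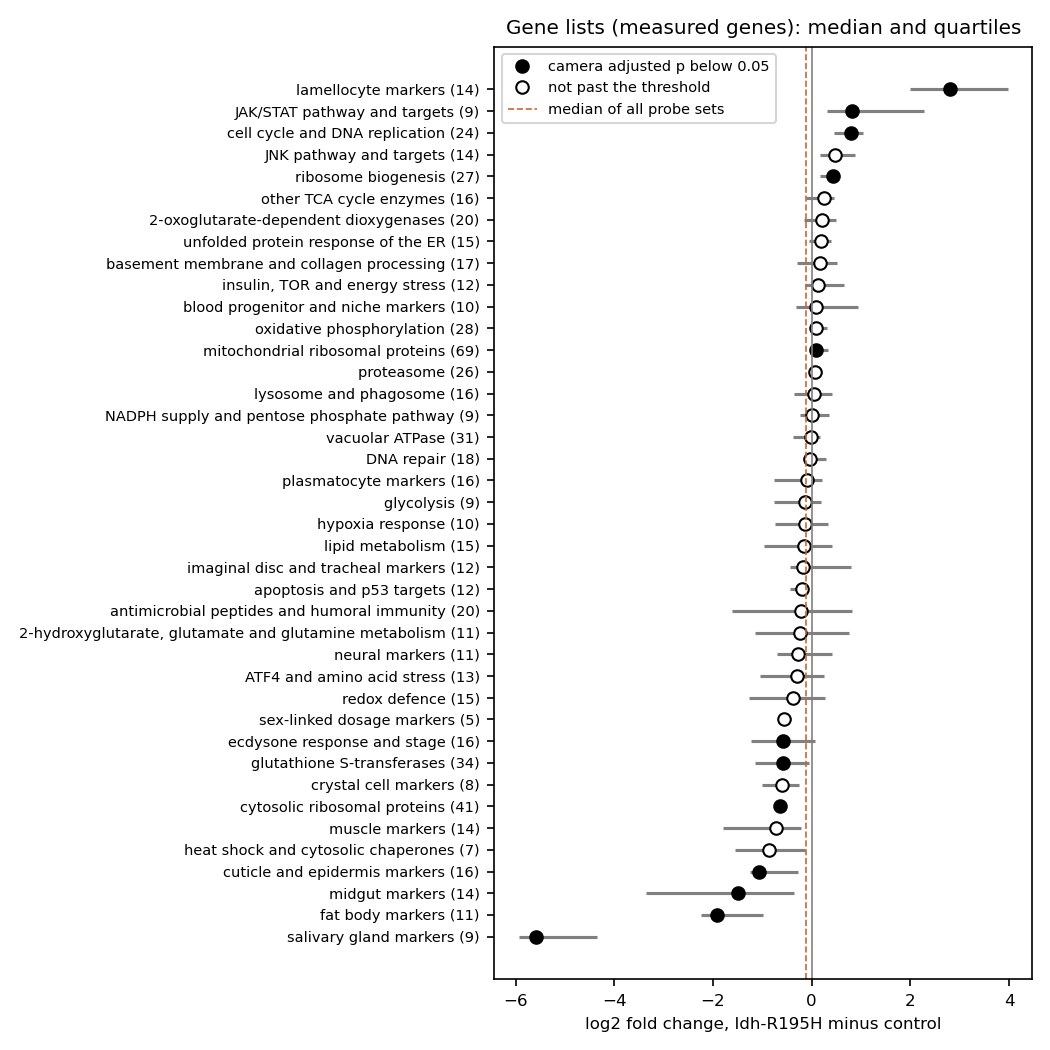
Median log2 fold change (points) and quartiles (lines) of the members of each of 40 tested gene lists, Idh-R195H minus control, with the number of measured genes in parentheses; filled points passed the camera test with a preset correlation, and the dashed line marks the median of all probe sets at -0.11. Lamellocyte markers stand highest, at 2.79, and salivary gland markers lowest, at -5.59.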

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

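The tests of marker lists, spike-in controls and RNA quality in this part were chosen after the results were seen; those on other splits of the arrays and on chromosomes were set beforehand.

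Of 183 array controls left out of the tests, 1 was higher and 17 were lower at an adjusted p below 0.05 when fitted with the other probe sets. Of the 61 bright ones, 10 had all Idh-R195H arrays above all control arrays (chance gives 10% for both directions together). The passing one was a probe set for the middle of the GAPDH transcript, with a log2 fold change of 1.16. Its companions for the 5' and 3' ends were at 1.32 and 0.96, also with all Idh-R195H arrays above all control arrays, whereas a second series of GAPDH controls was at -0.01 for the middle, 0.08 for the 5' end and -0.46 and -0.84 for the 3' end. The gene-specific direction of GAPDH is therefore not settled by these controls.

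Only 10 splits of the 6 arrays into groups of 3 exist, too few for a share under 0.05. The real split gave 584 changed probe sets and the highest of the others gave 0; 1 of 10 splits reached the real count. For gene lists, the real split gave 12 shifted lists, which 1 of 10 splits reached, and the highest of the others gave 10.

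The salivary gland, fat body, midgut and cuticle lists were lower in Idh-R195H hemocytes, with 9 of 9, 11 of 11, 11 of 14 and 14 of 16 members negative. With an estimated correlation these calls were lost (adjusted p = 0.686 for the first 3 and 0.537 for cuticle, against lowest values of the alternatives of 1.51e-09, 3.46e-06, 0.000653 and 0.00478). If hemocytes themselves express none of these markers, which was not checked, the sizes argue against a single dilution of all other tissues by a larger share of hemocytes. Among members with a control intensity above 1000, 7 salivary gland markers averaged a log2 fold change of -5.63 and 6 fat body markers -1.91. The difference was -3.725, with an SE of 0.34 over members and 1.201 over arrays. By array, the salivary gland mean minus the fat body mean was -2.89, -0.13 and -0.07 on control replicates 1, 2 and 3. On Idh-R195H replicates 1, 2 and 3 it was -4.495, -3.59 and -6.18. Control replicate 1 lay closer to Idh-R195H replicate 2 than to the other controls, so the size of the difference rests largely on control replicates 2 and 3. Most cuticle and midgut markers were too dim for this comparison. Carry-over that varied between pools predicts a wide spread inside the control group. There 2 of the 4 lists passed the limit set for variation between control arrays against 10000 expression-matched random lists. These were salivary gland markers, with an SD of 1.94 against a random median of 0.18 (Sgs3 at 4505.2, 52842.5 and 52056.0), and midgut markers, with 0.82 against 0.22, at percentiles of 100 and 99.9, while the fat body list was at 96.2 and the cuticle list at 27.8. Between Idh-R195H arrays the salivary gland, fat body and midgut lists were all at 100 and the cuticle list at 16.2. The random lists held genes drawn independently, so any list whose genes vary together can exceed them. This spread therefore cannot tell carry-over from a difference in stage or in expression between pools. Hemocytes were shaken out of opened larvae, and the labels describe no cell sorting. Whether carry-over also produced the difference between genotypes stays open, as does a difference in developmental stage or in those tissues' own expression, which was not tested.

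Lamellocyte markers rose by a median of 2.79. Array scaling as the whole cause is argued against, because under quantile normalization the list's median stood 2.88 ± 0.48 (SE over members) above that of all probe sets. RNA degradation or incomplete copying in the control samples may contribute. Among the 3 control arrays the list, relative to the array median, fell by 0.92 ± 0.34 (SE over 14 members) per log2 unit of the Act5C ratio. This was a slope of -0.917, although 5 of the 14 members went the other way. Over the gap between genotypes that slope reaches 0.95 ± 0.35, against a list difference of 3.21, but it rests on 3 arrays and an extrapolation. The array medians were at intensities of 80.2, 107 and 104 on control replicates 1, 2 and 3, so part of the slope lies in that reference. These SE values are over genes measured on the same 3 arrays and do not give the error of the slope over arrays. The polyA controls thr and dap, which were added to the RNA, had ratios of 8.4 ± 2.8 and 8.8 ± 1.7 on control arrays. On Idh-R195H arrays these were 4.6 ± 0.2 and 6.7 ± 0.9 (SD, n = 3 each). The ratio therefore cannot separate degradation of larval RNA from incomplete copying. Hybridisation controls were dimmer on Idh-R195H arrays, which is opposite in direction to the rise of the list. Scaling on them could therefore only raise the list's median, which became 3.74 ± 0.49 (SE over members), with the lowest member at 1.98. That scaling is no separate test of array brightness. A batch of another kind that coincides with genotype, such as in collection or labelling, cannot be told apart from genotype, since the labels give no batch. Of the bright polyA controls, repeated probe sets for dap, lys, phe and thr, 24 of 24 were lower on all Idh-R195H arrays than on any control array. So were 13 of 14 hybridisation controls, with a median log2 difference of -0.95 against -1.39 for the polyA controls. The part beyond this shared offset was not computed, so these controls do not show at which step a batch would lie. An effect of Idh-R195H on hemocyte classes stays open together with such a batch.

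The genotype labels separate the transgene from the driver by a semicolon, a notation that by convention moves on to the next chromosome, so chromosome 3 may differ in background between the genotypes. Genes of chromosome 3 made up 49.6% of changed and 44.5% of other genes, an odds ratio of 1.22 (95% interval 1.01 to 1.48, Fisher's exact test, two-sided p = 0.0376). This met the limit set beforehand for chromosome 3, a p below 0.05. Adjusted over the 4 chromosomes tested, which that limit did not include, p was 0.122, so the excess is small and does not pass that correction. The location of the transgene is read from notation only, and 99.6% of changed genes had a chromosome.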

How the results depend on the processing

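The alternatives with spike-in scaling and with 1 control array were chosen after seeing the data. The main counts were 584 changed probe sets, 356 higher and 228 lower. The counts of changed, higher and lower probe sets were 1300, 723 and 577 without dim probe sets, 1253, 667 and 586 with an intensity trend and robust prior, and 7489, 3337 and 4152 with array weights, whose estimate did not converge and gave control replicate 2 a weight of 10.9 against 0.181 and 0.252 for the other controls. With a constant of 16 they were 888, 508 and 380, after scaling on hybridisation controls 6252, 6081 and 171, and with control replicate 1 alone (assumed to vary like the Idh-R195H arrays) 346, 278 and 68. Centring on array medians gave 429, 318 and 111, so 74.1% rather than 61.0% of calls were higher, and quantile normalization gave 493, 329 and 164 (66.7% higher). An adjusted p below 0.1 gave 1250 changed, a 2-fold minimum 584, and 1 probe set per gene 674. Leaving out 1 array gave from 11 to 870 changed, 11 to 543 higher and 0 to 327 lower; the lowest were without Idh-R195H replicate 2 (2577 at an unadjusted p below 0.05) and the highest without control replicate 1, and the others were 86 and 68 without Idh-R195H replicates 1 and 3, and 155 and 300 without control replicates 2 and 3. Fewer arrays leave fewer residual degrees of freedom; the cause of the other differences was not tested.

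The replicate numbers were not taken to pair the samples: deviations from the group means correlated at 0.03, 0.02 and -0.07 for equal numbers across probe sets, and not every array correlated best with its own number. With the replicate block limma called 0 probe sets, 0 higher and 0 lower (3088 at an unadjusted p below 0.05), and Idh kept 1.30 with an adjusted p of 0.173, while 12 lists passed.

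The log2 fold change of Idh ran from 1.23 to 1.35 over the arrays left out, past the threshold only without control replicate 1, and was 1.56 with median centring and 1.38 with 1 control array, past it in neither, and 2.25 after spike-in scaling, past it (adjusted p from 0.00112 to 0.173 over all alternatives). Of the other 56 named genes past the threshold, 0 passed in every alternative, which the replicate block alone fixes, since it called 0 probe sets. ItgaPS4 and PPO3 passed in 14 of 15 alternatives. The sign of the 56 genes, which their choice largely fixes, was not turned in the alternatives where they were tested. Of them 49 passed with quantile normalization, 42 with median centring, 56 with a trend, with weights and with a constant of 16, 49 after spike-in scaling, 48 without dim probe sets (8 were filtered out), 19 with 1 control array, and 46, 20 and 26 without control replicates 1, 2 and 3 and 14, 2 and 12 without Idh-R195H replicates 1, 2 and 3. Genes not past the threshold that turned sign were PPO2 (0.0898), RpL24-like (0.16) and mRpS6 (0.19) after spike-in scaling, and RpL37-2 (0.41), RpL22-like (0.48) and RpS5b (0.26) with 1 control array; the cause was not tested.

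Of 40 lists 12 passed in the main test, and 0 passed with an estimated correlation (3 at an unadjusted p below 0.05, lowest adjusted p 0.0592), 6 lists with 1 control array, 9 with fry, 10 with quantile normalization and 15 with median centring; leaving out 1 array gave 9 to 13. Ribosome biogenesis turned downward relative to other genes with 1 control array, with a median of 0.0331 (adjusted p 0.92; the cause was not tested). The lamellocyte and cell cycle calls were lost only with an estimated correlation. Signal near background limits the dim probe sets: from 49.0% to 54.1% of an array lay below an intensity of 100.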

Other observations

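Gene families defined by a shared symbol stem, with at least 10 measured genes each, were tested with camera after the data had been seen, and 7 of 47 families passed with a preset correlation and none with an estimated one. Besides the ribosomal protein families RpL and RpS, the cytochrome P450 genes (Cyp) were lower as a group relative to other genes. Their median log2 fold change was -0.53 over 83 genes (camera adjusted p = 0.00107, or 0.589 with an estimated correlation). After scaling on hybridisation controls it was 0.42, against 0.84 for all probe sets. The higher fat body and midgut signal of the control arrays (median log2 fold changes of -1.91 and -1.49) moved with this group. Singly, 6 of them were lower and 3 higher. Among these, chosen after their values were seen, Cyp6a2 went from 68.3 to 408.5 (log2 fold change 2.56 ± 0.25, SE) and Cyp6a20 from 67.3 to 239.9, while Cyp6a17 went from 1418.3 to 312.1 (-2.19 ± 0.27) and Cyp4e2 from 8062.7 to 2663.2 (mean intensities, n = 3 each).

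Families of vesicle transport and the nuclear pore were slightly higher with the deposited scaling and after quantile normalization. Median centring and scaling on hybridisation controls raised every log2 fold change by the same amount, so they are no separate check of the sign. Vacuolar protein sorting genes (Vps) had a median of 0.22 with 26 of 27 positive (adjusted p = 0.00212), nucleoporin genes (Nup) 0.29 with 18 of 20 positive (adjusted p = 0.00229) and Sec genes 0.29 with 13 of 17 positive (adjusted p = 0.0233). With an estimated correlation the adjusted p was 0.709 for each of these. The higher Act5C ratios of the control arrays (4.78 against 2.28) and their higher salivary gland and fat body signal (median log2 fold changes of -5.59 and -1.91) moved with these families. Nup35, chosen after its value was seen, rose from 1018.0 to 2170.6 (log2 fold change 1.09 ± 0.19, SE).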
